A study of Mus musculus with 2 samples.

How the data were processed

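H3K4me3 chromatin immunoprecipitation and sequencing was carried out on limb tissue of mouse embryos at embryonic day 11.5 in 2 biological replicates, with 109 embryos pooled in replicate 1 and 88 in replicate 2 and fragments of 300 to 500 bp, per the labels. The sequencing reads were processed by the authors, and the deposited peak lists were the starting point here. There were 4 lists on mm10: 1 for each replicate, 1 for the pooled replicates and 1 of replicated peaks, which the accompanying text files of the deposit describe as derived from the pooled list and both replicate lists. The aligner, the peak caller, their versions and the rule for a replicated peak are not given in the sources used here. All 20422 replicated peaks on the main chromosomes were also in the pooled list with the same coordinates and signal. Of these, 19500 overlapped a peak of both replicate lists, so the others had no overlapping peak in at least 1 replicate. An overlap of at least 50% with a peak of each replicate was lacking for 961.

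Each deposited list gives for every peak its position, a signal value whose normalization is not given in the sources used here, and −log10 values of p and q as deposited by the authors. The lowest −log10 p was 2.23 in replicate 1, 2.01 in replicate 2 and 2.05 in the pooled and replicated lists, so weak peaks were kept by the authors, and 11.2% of replicate 1 peaks and 22.3% of replicate 2 peaks had a −log10 q under 2. Peaks were used as deposited, without a further filter. The number of reads per library is unknown, so no interval that needs depth was computed; Wilson intervals at 95% describe shares of peaks or genes and cover counting error only. Replicates were separate pools of embryos, so their spread includes biological variation, but an SD over n = 2 is imprecise.

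Gene models were taken from GENCODE M21 on GRCm38, the assembly behind mm10, and sequence from GRCm38.p6. Over the 21 chromosomes compared, 0 peaks and 0 genes ended past the end of a chromosome. Analysis was limited to chromosomes 1 to 19, X and Y, which left out 17, 13, 14 and 9 peaks of the replicate 1, replicate 2, pooled and replicated lists. A TSS window was 1000 bp on either side of the 5′ end of any annotated transcript of the 21938 protein-coding genes, and a gene was marked when a peak overlapped a window by at least 1 bp. Domains were replicated peaks joined across gaps of at most 1000 bp, and a gene took the widest domain touching one of its windows. The CpG ratio was the observed over expected CpG count in 1000 bp around the 5′ end of the gene, with 0.6 as the minimum for a CpG-rich promoter. Distal peaks had no edge within 5000 bp of a TSS of any gene type. Coordinates are 1-based.

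Overlap between replicates and between peaks and promoters was tested one-sided against 200 random placements of the peaks within their chromosomes. Marking of gene lists, CpG classes and the widest 5% of domains were tested with two-sided Fisher's exact tests. Where a cell of such a test was empty, a constant was added to every cell for the odds ratio, not for p. Domain width was tested with two-sided permutation tests against 10000 random lists of marked genes. P-values were adjusted by the Benjamini-Hochberg method over the 19 lists, or over the 15 lists with at least 5 marked members, at a threshold of 0.05. All of these tests run across peaks or genes within 1 group, and neighbouring genes can share a peak, so the p-values do not describe variation between embryos. The gene lists and named genes were fixed before the data were examined: a set of limb, lineage and control genes, the 20 widest domains (1 gene per domain, nearest the centre), the 2 marked members with the widest domain and the first 2 unmarked members of each list, the 5 strongest replicate-only promoters in each direction, the 5 strongest distal peaks and every member of a count of 5 or fewer. Further members of the lists and of the Hox clusters were named after their values were seen. In the lists, 46 of 47 limb transcription factor symbols, 19 of 20 terminal epidermal and 17 of 20 imprinted symbols matched a protein-coding gene, and all symbols of the other lists matched.

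The procedures were tested on simulated data. All 200 genes given a planted peak were recovered, and of the 21938 genes 0 were called away from every planted peak. Genes whose windows touched a planted peak were not counted as false calls. Planted peaks covered the 5′ end and background peaks were kept off all TSS windows, so both results follow from the construction and only check the code. The 50 simulated depleted lists were called in 100% of cases, with 1 of 150 random lists called. The 20 lists whose widths were doubled in the 14220 marked genes (fold 2) were called in 100% of cases. Of 80 random lists 0 were called, and 4 had an unadjusted p under 0.05. For the broadest domains, 10 simulated lists were called in 100% of cases and 1 of 90 random lists was called.

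Alternatives fixed before the data were examined were a −log10 q of at least 2 or 5, an overlap of at least 50%, lists of equal length, ranking by −log10 p, the pooled list, each replicate list alone, windows of 500 and 2500 bp, the 5′ end of the gene as the only TSS, a CpG ratio of 0.75, no joining of peaks or joining across 3000 bp, random lists matched on CpG ratio, summed peak width, the widest 2% or 10%, distances of 2000 and 10000 bp and protein-coding genes only. Matching on CpG-dense sequence or on deciles of peak signal, 1 gene per domain and a comparison within CpG-poor promoters were added after seeing the data. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.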

Results

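Trimethylation of histone H3 at lysine 4 (H3K4me3), a chromatin mark of gene promoters, was mapped by chromatin immunoprecipitation and sequencing in limb tissue of mouse embryos at embryonic day 11.5, a stage at which the limb buds are being patterned. The series held 1 group with 2 biological replicates. Replicate 1 was made from a pool of 109 embryos and replicate 2 from a pool of 88 embryos, of mixed sex. With no second tissue, stage or treatment, the comparisons that the design implies were how far the replicates matched and which promoters and regions carried the mark. The authors' peaks were listed on the mm10 build for each replicate, for the pooled replicates and as a list of replicated peaks. Replicate 1 had 25444 peaks with a median width of 898 bp, and replicate 2 had 33230 peaks with a median width of 604 bp. The pooled list held 24583 peaks and the replicated list 20431 peaks, with a median width of 1330 bp and 30.2 Mb covered. The numbers of reads behind the lists were not analysed here, so the depth of each library is unknown. The signal per peak is the authors' value and was used only to describe or rank peaks within a list.

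The replicates shared their strong peaks and differed in their weak ones. Of the replicate 1 peaks on chromosomes 1 to 19, X and Y, 21719 of 25427 (85.4%, 95% Wilson interval 85.0% to 85.8%) overlapped a replicate 2 peak, against a mean of 2.61% and a maximum of 2.88% over 200 random placements (one-sided permutation test, p = 0.00498, the smallest that 200 placements can give). In the other direction 21271 of 33217 replicate 2 peaks overlapped (64.0%, interval 63.5% to 64.6%). The base pairs covered by both lists made up a Jaccard index of 0.736. Across the 21719 paired peaks, which are not independent replicates, the signal ranked with a Spearman rho of 0.794. In the strongest 10% of either list 100% of peaks were found in the other replicate, whereas in the weakest 10% the share was 42.2% for replicate 1 and 12.2% for replicate 2. The 11946 peaks private to replicate 2 had a median width of 238 bp and a median signal of 3.08, against 1244 bp and 19.6 for the shared peaks of that list. Of these private peaks 23.3% lay at the transcription start site (TSS) of a protein-coding gene, compared with 74.3% of the shared ones. Only 1 peak had identical coordinates in both lists.

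**Figure D1:**
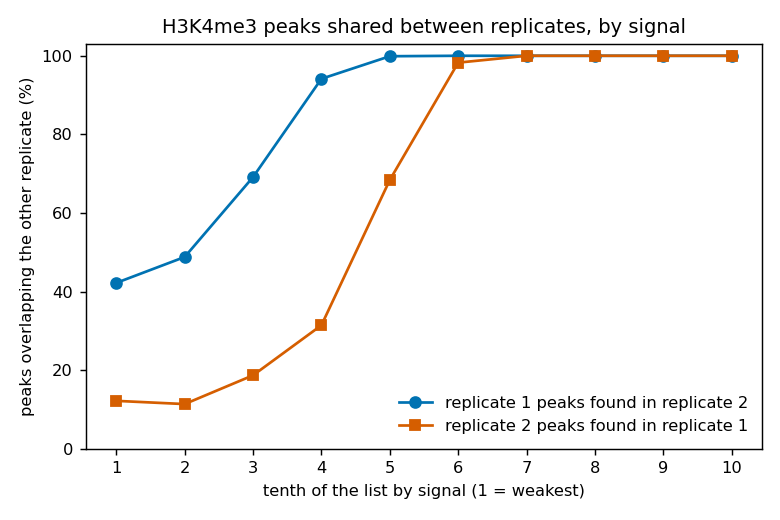
Share of peaks in percent (vertical axis) of each replicate list that overlap a peak of the other replicate, by decile of the list ranked on signal (horizontal axis, 1 is the weakest); circles are replicate 1 peaks and squares replicate 2 peaks. The share is 42.2% and 12.2% in the weakest decile and reaches 100% in the strongest decile of both lists.

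The mark lay mostly at promoters. Of the replicated peaks, 14917 of 20422 (73.0%, 95% Wilson interval 72.4% to 73.6%) overlapped the 1000 bp on either side of a protein-coding TSS, against 6.32% on average and at most 6.73% for the same peaks placed at random (one-sided permutation test over 200 placements, p = 0.00498, the smallest possible). The share was 65.6% in the replicate 1 list, 56.0% in the replicate 2 list and 65.7% in the pooled list. A protein-coding gene was called marked when a peak overlapped such a window by at least 1 bp. By this rule 14220 of 21938 protein-coding genes (64.8%) were marked in the replicated list, and the replicate lists marked 14394.5 ± 176 genes (mean ± SD, n = 2). Both replicate lists marked 14170 genes in common, and 7319 genes were marked in neither.

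Genes with a promoter rich in CpG dinucleotides at their 5′ end were marked far more often than genes with a CpG-poor one. The CpG class was taken at the 5′ end of the gene only, whereas a gene could be marked at any of its TSSs. A gene of the CpG-poor class can therefore be marked at a TSS whose CpG ratio was not measured. Among the 10076 genes with an observed-to-expected CpG ratio of at least 0.6 over the 1000 bp around the 5′ end of the gene, 9892 were marked (98.2%, 95% Wilson interval 97.9% to 98.4%). Among the 11862 CpG-poor genes 4328 were marked (36.5%, interval 35.6% to 37.4%). The log2 odds ratio was 6.55 ± 0.11 (SE), and the two-sided Fisher's exact p was too small to be represented. Marked genes of the CpG-rich class also had wider domains, with a median of 2033 bp against 1417 bp, where a domain is a run of replicated peaks no more than 1000 bp apart. This comparison runs across genes, which are not replicates.

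Regulators of limb development were marked almost without exception. All 46 limb transcription factors of a list fixed beforehand were marked in the replicated list and in each replicate list, compared with 64.7% of the remaining protein-coding genes (two-sided Fisher's exact test, Benjamini-Hochberg adjusted over 19 lists, adjusted exact p = 1.6e-08). They included Tbx5 (domain on chromosome 5 from 119829117 to 119843893) and Tbx4, T-box factors of the forelimb and the hindlimb, Pitx1 (chromosome 13, 55823861 to 55837955), a hindlimb regulator, Hand2, a posterior regulator, and Lmx1b, a regulator of dorsal identity. All 39 limb signalling genes were marked (adjusted exact p = 2.99e-07), among them Shh, Fgf10, Grem1, Gli3 and Ptch1, the receptor of the hedgehog pathway. Of the 39 Hox genes 38 were marked (adjusted exact p = 6.37e-06); the exception, Hoxb1, had a peak in replicate 2 alone, with a signal of 3.46. The ectoderm and apical ridge list had 25 of 28 members marked (adjusted exact p = 0.0074), including Fgf8 and Wnt7a, while the keratin genes Krt14 and Krt5 and the epidermal regulator Trp63 were not. CpG-rich promoters, 98.2% of which were marked, made up 50% to 73.9% of these 4 lists, so a part of the excess went with CpG class. Among genes with a CpG-poor 5′ end, 36.5% marked in all, the counts were 12 of 12 limb transcription factors and 11 of 11 signalling genes. They were 13 of 14 for Hox and 11 of 14 for ectoderm genes. These counts do not show that the CpG-poor 5′ end itself carried the mark. Fgf10, with a CpG ratio of 0.345, starts at 118669791 on chromosome 13, and its domain starts at 118713061. Within the chondrogenic and skeletal list, Sox9 and the cartilage collagen gene Col2a1 were marked and Bglap and Col10a1 were not.

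Lists of 7 other tissues or mature cell types were marked less often than the remaining genes. Of the adult organ products 2 of 29 were marked (Opn1sw and Ucp1, adjusted exact p = 9.22e-10), and of the olfactory receptor genes 1 of 1135 (Olfr94, adjusted exact p too small to be represented). The lists for terminal epidermal differentiation (3 of 19, adjusted exact p = 4.31e-05), pluripotency and germline (4 of 21, adjusted exact p = 5.45e-05), blood and macrophages (8 of 29, adjusted exact p = 9.86e-05), liver and endoderm (8 of 24, adjusted exact p = 0.00359) and heart (7 of 20, adjusted exact p = 0.0113) were also below the rest. The pluripotency and germline members marked were Lin28a, Esrrb, Dazl and Prdm14, and the epidermal ones were Lor, Krt10 and Krt1. The domains at Lor, Krt10, Krt1 and Olfr94 lay over the gene body and did not reach the 5′ end of the gene. Alb, the albumin gene, Afp, Gata1, the erythroid regulator, Alas2, Myh6 and Myh7 had no replicated peak at a TSS. Most of these lists had few CpG-rich promoters, with 0% in the adult, epidermal and olfactory lists, 3.45% in the blood list and 42.9% in the pluripotency list, against 73.9% in the limb transcription factors. Among genes with CpG-poor promoters alone, a comparison chosen after seeing the data, the deficit kept an adjusted exact p below the threshold for the adult organ products (0.00135) and olfactory receptors (5.95e-235), and not for the epidermal (0.127), pluripotency (0.587), blood (0.29), liver (0.211) and cardiac lists (0.496). In the pluripotency list the unmarked genes were not confined to CpG-poor promoters, as 1 of its 9 CpG-rich members (Dazl) and 3 of its 12 CpG-poor members (Lin28a, Esrrb and Prdm14) were marked.

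The remaining lists did not all follow the limb lists. The myogenic list had 14 of 25 members marked (adjusted exact p = 0.426); Pax3, Myod1 and Lbx1 were among the marked members and Myog, Acta1 and Actc1 among the unmarked ones, as was Myf5, which was marked in replicate 2 alone. The endothelial list had 17 of 24 marked (adjusted exact p = 0.671), with Kdr, Fli1 and Ets1 marked and Cdh5 and Emcn not. Peripheral nerve and neural crest genes were marked in 17 of 22 cases (adjusted exact p = 0.3), among them Sox10, Ngfr and Pou4f1 but not Dct or Fabp7, and chondrogenic and skeletal genes in 19 of 24 (adjusted exact p = 0.236). Among genes with CpG-poor promoters alone, 14 of 19 chondrogenic and skeletal genes were marked (adjusted exact p = 0.00283). Regulators of the central nervous system, a tissue outside the sample, were marked in 22 of 24 cases (adjusted exact p = 0.00717), Pax6 and Sox1 included and Dbx1 and Neurod6 not. This call ended at a −log10 q of at least 5, with windows of 500 bp and with the 5′ end of the gene as its only TSS (adjusted exact p from 0.00147 to 0.461 over all alternatives). All 28 housekeeping genes (adjusted exact p = 2.73e-05) and all 24 cell cycle genes (adjusted exact p = 9.15e-05) were marked, as were 16 of 17 imprinted genes (adjusted exact p = 0.0121), with Ndn the exception. CpG-rich promoters made up 75% of the central nervous system, 75% of the housekeeping and 83.3% of the cell cycle list, so a part of these excesses went with CpG class. Among the genes with CpG-poor promoters in these lists, 5 of 6, 7 of 7 and 4 of 4 were marked. The imprinted call ended with the 5′ end of the gene as the only TSS (adjusted exact p from 0.00199 to 0.283 over all alternatives), and the cardiac call ended with windows of 2500 bp, without replicate 1 and among CpG-poor promoters (0.00935 to 0.496).

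**Figure D2:**
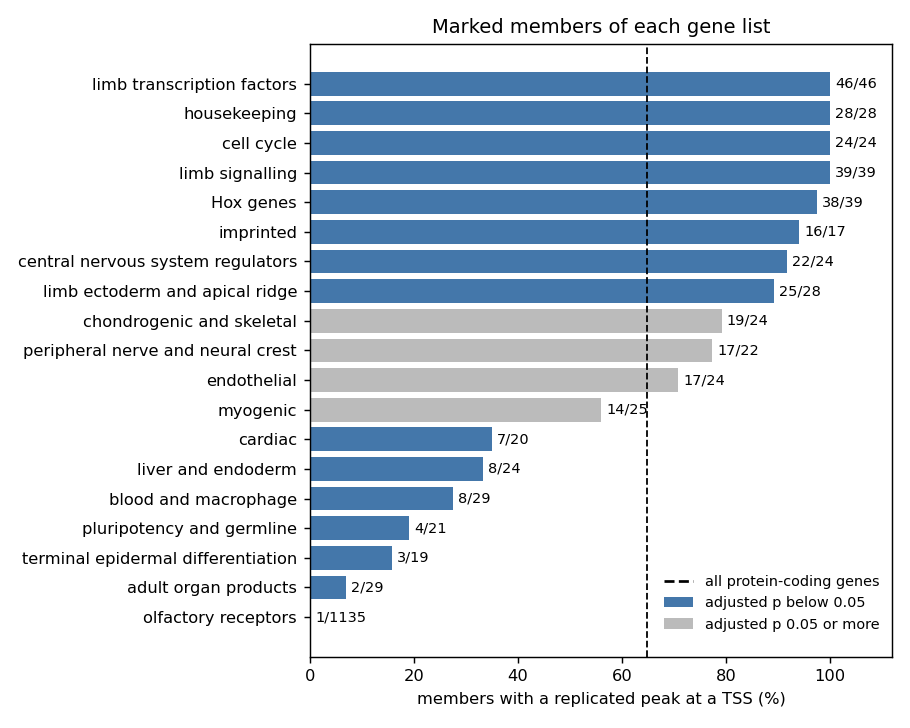
Percent of the members of each gene list with a replicated peak within 1000 bp of a TSS (bars, horizontal axis), with the number marked out of all members beside each bar; the dashed line is the share of all protein-coding genes, 64.8%. Blue bars have an adjusted exact p below 0.05, grey bars do not; the limb transcription factor and limb signalling lists reach 46 of 46 and 39 of 39, and the olfactory receptor list 1 of 1135.

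The limb regulators stood apart most clearly in the width of the marked domain. The median domain at the 46 limb transcription factors was 5896 bp in the replicated list and 6052 ± 739 bp over both replicate lists (mean ± SD, n = 2), against a median of 1867.5 bp over random lists of 46 marked genes. In a two-sided permutation test with 10000 random lists, Benjamini-Hochberg adjusted over the 15 lists with at least 5 marked members, the adjusted p was 0.00075, the smallest reached over these lists. The Hox genes (median 5023 bp, replicates 5223 ± 449 bp; 3269 bp with 1 gene per domain, 3282 bp without joining of peaks and 37190 bp with joining across 3000 bp), the limb signalling genes (3663 bp, replicates 3688.5 ± 142 bp) and the imprinted genes (3323.5 bp, replicates 3123 ± 379 bp) had the same adjusted permutation p of 0.00075. Wider domains than at random were also found at cell cycle genes (median 2700 bp, adjusted permutation p = 0.0024), where Ccnd2 and Ccnd1, which encode D-type cyclins, had the widest at 7644 and 6255 bp, and at chondrogenic genes (2529 bp, adjusted permutation p = 0.0261). The median over central nervous system regulators, 1375 bp, was below that of random lists (adjusted permutation p = 0.0255). Their peaks were weak, with a median signal of 8.92 against 33.6 over all marked genes, and against random lists matched on peak signal the median was not lower (log2 ratio 0.43, adjusted permutation p = 0.081). The myogenic median of 1328.5 bp was lower as well (adjusted permutation p = 0.0412), but the replicate lists alone gave medians of 1651 and 2268 bp, adjusted permutation p of 0.793 and 0.398 and, in replicate 2, the opposite direction; the call ended under 9 of 11 alternatives (0.006 to 0.954), and the direction also turned with random lists matched on peak signal. The medians of the housekeeping (2134.5 bp, adjusted permutation p = 0.276), ectoderm (2334 bp, 0.0677), liver (2226.5 bp, 0.4), endothelial (1858 bp, 0.981), blood (1627.5 bp, 0.466), nerve and crest (1582 bp, 0.292) and cardiac lists (1423 bp, 0.276) missed the threshold. Against random lists matched on peak signal, a setting chosen after seeing the data, the ectoderm (log2 ratio 0.95, adjusted permutation p = 0.0005), liver (0.70, 0.0327) and endothelial lists (0.58, 0.0327) were wider. The pluripotency and germline list had 7 marked members without replicate 1, and its median of 493 bp there was narrower than at random (log2 ratio -1.99, adjusted permutation p = 0.0008). Other alternatives also gave calls: the cardiac list was narrower in each replicate list alone (adjusted permutation p = 0.0494 and 0.0341) and with matching on CpG-dense sequence (0.047), and the nerve and crest list without joining (0.042). The housekeeping list was wider without replicate 1 (adjusted permutation p = 0.00411) and with joining across 3000 bp (0.0015), the ectoderm list with that joining (0.0006), with matching on CpG ratio (0.00771) and with 1 gene per domain (0.0407), and the liver list with that joining (0.00787). The calls for the limb transcription factors, limb signalling, Hox and cell cycle genes held under all alternatives run. The chondrogenic call ended without replicate 1, at a −log10 q of at least 5 and with summed peak width. It also ended, with the direction turned, without joining of neighbouring peaks (adjusted permutation p from 0.0005 to 0.917 over all alternatives). The central nervous system call ended at a −log10 q of at least 5 and with summed width. With the direction turned, it also ended when peaks up to 3000 bp apart were joined and against lists matched on signal (adjusted permutation p from 0.0006 to 0.591). The imprinted call ended without joining (adjusted permutation p from 0.0005 to 0.167).

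**Figure D3:**
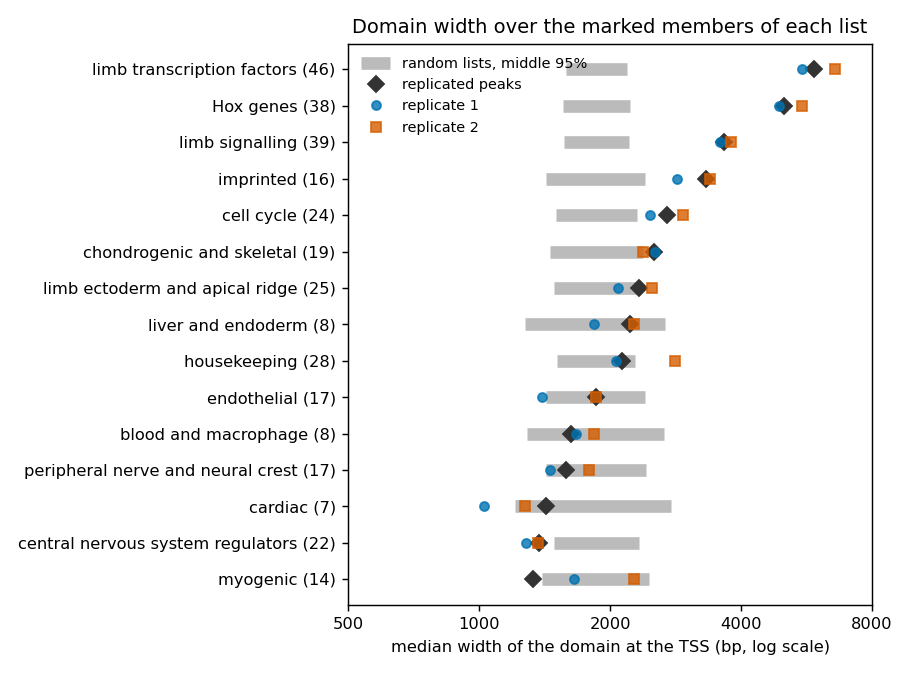
Median width in bp of the H3K4me3 domain at the TSS over the marked members of each list (horizontal axis, log scale; number of members in parentheses). Diamonds are the replicated peaks, circles replicate 1, squares replicate 2, and grey bars the middle 95% of 10000 random lists of the same size; the limb transcription factor (5896 bp), Hox (5023 bp) and limb signalling (3663 bp) medians lie to the right of the grey bars.

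The broadest domains were enriched for limb regulators and Hox genes. Promoter domains in the widest 5% were at least 4027.5 bp wide; they were 636 of 12706 domains and reached 789 of the 14220 marked genes. Of the marked limb transcription factors 33 of 46 (71.7%) had such a domain, against 5.33% of other marked genes (two-sided Fisher's exact test, adjusted exact p = 1.46e-30). The figures were 23 of 38 Hox genes (60.5%, adjusted exact p = 5.04e-19) and 17 of 39 limb signalling genes (43.6%, adjusted exact p = 3.04e-11). Smaller excesses passed the threshold for chondrogenic (Sox9, Col2a1, Runx2, Sox6 and Col11a2, 5 of 19, adjusted exact p = 0.0118), imprinted (Igf2, Grb10, Peg3 and Mest, 4 of 16, 0.0301) and housekeeping genes (Rpl13a, Polr2a, Tbp, Tubb5 and Eef2, 5 of 28, 0.044). Of the central nervous system regulators 0 of 22 had one (adjusted exact p = 0.677), and of the nerve and crest genes 0 of 17. The excess missed the threshold for the myogenic (Six1, Lbx1 and Six4, 3 of 14, adjusted exact p = 0.0839), cardiac (Gata6 and Hand1, 2 of 7, 0.101), ectoderm (Fgf9, Dlx5 and Dlx2, 3 of 25, 0.238) and cell cycle lists (Ccnd2, Ccnd1 and Rrm2, 3 of 24, 0.238). It also missed it for the blood (Runx1, 1 of 8, adjusted exact p = 0.458), liver (Gata6, 1 of 8, 0.458) and endothelial lists (Fli1, 1 of 17, 0.677). The domain of Hand1 measured 1023 bp in replicate 1. The cell cycle list passed it without replicate 1 (adjusted exact p = 0.0263), without joining (0.0243) and with joining across 3000 bp (0.039), and the ectoderm (0.0144) and liver lists (0.031) with joining across 3000 bp. Genes within a shared domain take its width and are not independent, but with 1 gene per domain, a setting chosen after seeing the data, the Hox count was 9 of 24 (adjusted exact p = 6.38e-06). The chondrogenic and housekeeping calls ended at a −log10 q of at least 5, without joining, with joining across 3000 bp and in the widest 2% (adjusted exact p from 0.00282 to 0.184 and from 0.00666 to 1 over all alternatives).

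The widest single domains lay over the Hox clusters and at further developmental regulators. The widest, 51587 bp on chromosome 6 from 52215648 to 52267234 (replicates 51350 ± 344 bp, mean ± SD, n = 2), ran over Hoxa7, Hoxa9, Hoxa10, Hoxa11 and Hoxa13. The domain named by Hoxd11 and also holding Hoxd13 covered 35275 bp of chromosome 2 from 74666040 to 74701314 (replicates 35165 ± 29.7 bp), and that named by Hoxc9 covered 25811 bp of chromosome 15 (replicates 24948 ± 1067 bp). Outside the clusters came Lmx1b with 17811 bp (replicates 14478 ± 4287 bp), a domain of 16282 bp that touches TSS windows of both Rsrc1 and the limb regulator Shox2 (replicates 11298 ± 812 bp), Tbx2 with 15717 bp, Tbx5 with 14777 bp and Pitx1 with 14095 bp. Kdm6b, which encodes a histone H3K27 demethylase, Bahcc1 and Tnrc18 followed at 13764, 13745 and 13330 bp. Lhx9, Tbx15, Nr2f2, Hand2, Meis2, Hoxa6, Ptch1, Igf2 and Skida1 made up the rest of the 20 widest, between 11468 and 13231 bp. The Hoxa6 domain ended at 52214641 and counts apart from the widest domain only because the gap between them was just past 1000 bp. The width of a domain could differ between lists: Nr2f2 measured 12906 bp in the replicated list and 8338 ± 19.8 bp in the replicate lists. In replicate 1 Ptch1 and Skida1 measured 7635 and 6588 bp, and in replicate 2 they measured 12817 and 12422 bp. Tbx4, Prrx1 and Meis1 had domains of 10076, 9552 and 8035 bp, Sox9 and Col2a1 of 6675 and 5848 bp, Gli3 and Fgf10 of 5744 and 4508 bp.

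Domains at Shh, Fgf8, Wnt7a, En1 and Grem1 ranged from 1819 to 3151 bp in the replicated list. The median over all marked genes was 1866 bp. Shh, the signal of the zone of polarizing activity, had a domain of 3108 bp (replicates 3587.5 ± 681 bp) whose strongest peak had a signal of 3.42, against a list median of 20.5. The domain of Fgf8, a ligand of the apical ridge, was 1819 bp wide, that of Wnt7a, a ligand of the dorsal ectoderm, 2459 bp and that of En1, a regulator of the ventral ectoderm, 3151 bp, with signals of 16.6, 16.3 and 13.3. The En1 domain measured 2992 bp in replicate 1 and 5472 bp in replicate 2. Grem1, a BMP antagonist, had 2707 bp. The widely expressed genes Actb and Gapdh had domains of 2795 and 3432 bp with signals of 71.3 and 57.1. The muscle genes Pax3 and Myod1 had 1126 and 2429 bp with signals of 9.95 and 6.67, the endothelial gene Kdr 1961 bp, Sox10 993 bp, and Pax6, a regulator of eye and brain, 2099 bp with a signal of 7.62. Pax3 had 835 bp in replicate 1 and 2270 bp in replicate 2. Kdr had 2898 and 3859 bp. Nkx2-5, a cardiac regulator, and Pou5f1, a pluripotency factor, had no replicated peak and a peak in replicate 2 alone, and Myog, Gata1 and Alb had none in any of the replicate or replicated lists.

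The 4 Hox clusters differed in how much of their length the mark covered. Replicated peaks covered 63.2% of the HoxA cluster on chromosome 6 (52155590 to 52260880) and 49.99% of the HoxD cluster on chromosome 2 (74668310 to 74765142). They covered 39.5% of HoxC on chromosome 15 (102921103 to 103036852) and 16.4% of HoxB on chromosome 11 (96194316 to 96368256). The HoxB span includes the stretch between the end of Hoxb13 at 96197447 and the start of Hoxb9 at 96271457. Few replicated peaks lay there, so a part of the low HoxB share comes from the length of the span. Over both replicates the covered share was 61.1% ± 3.5 for HoxA, 49.1% ± 1.8 for HoxD, 37.9% ± 3.8 for HoxC and 15.5% ± 3.2 for HoxB (mean ± SD, n = 2). The order of the clusters was the same in each replicate and the gaps between them exceeded the replicate SDs; with 2 libraries no test across samples was made. In HoxD a single domain ran over Hoxd13 to Hoxd9, with separate peaks from Hoxd8 on, and in HoxA a single domain ran from Hoxa7 to beyond Hoxa13. The start of that HoxA domain, at 52215648, was set by the joining rule. The peak before it ended at 52214641, a gap just past the 1000 bp allowed. All 11 genes of HoxA, 9 of HoxD and 9 of HoxC were marked, and 9 of 10 in HoxB.

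**Figure D4:**
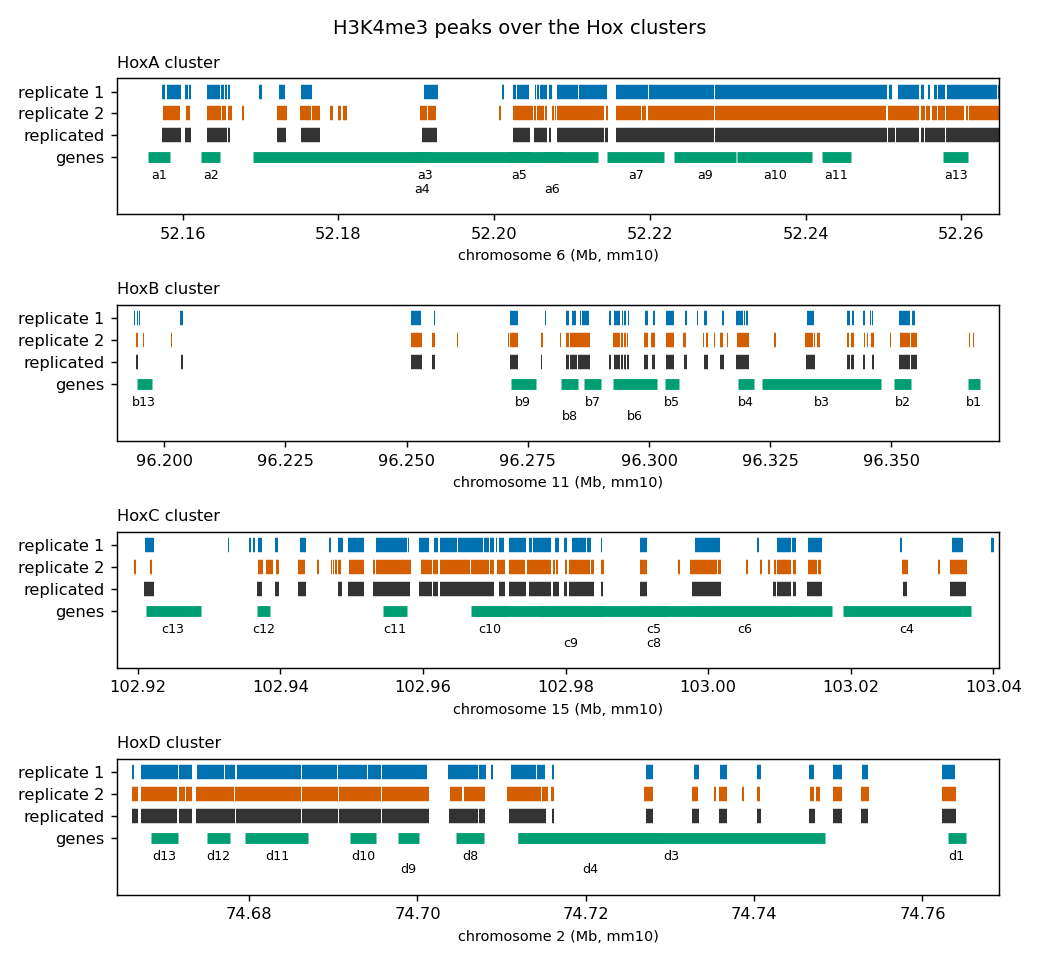
Map of the H3K4me3 peaks over the 4 Hox clusters (horizontal axis, mm10 position in Mb), with replicate 1, replicate 2 and replicated peaks as coloured blocks and gene extents in green below. Replicated peaks cover 63.2% of HoxA, 16.4% of HoxB, 39.5% of HoxC and 49.99% of HoxD, and are densest over Hoxa7 to Hoxa13 and Hoxd9 to Hoxd13 in both replicates.

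A minority of the peaks lay far from any annotated TSS. Of the replicated peaks 2345 of 20422 (11.5%, 95% Wilson interval 11.1% to 11.9%) had no edge within 5000 bp of a TSS of any gene type. Of these distal peaks 61.8% were intergenic, 24.7% lay in introns and 13.5% overlapped an exon. They were narrower and weaker than peaks at protein-coding TSSs, with a median width of 592 against 1614 bp and a median signal of 5.72 against 29.4. The 5 strongest were present in both replicate lists. They lay on chromosome 8 from 69715934 to 69717059, 5210 bp from Zfp869 (signal 54.7); in an intron of Tns3 on chromosome 11 from 8621763 to 8625285 (51.1); in an intergenic stretch of chromosome 9 from 32031654 to 32033795 (40.8); over an exon of Ccdc92b on chromosome 11 from 74637310 to 74639279 (39.7); and on chromosome 12 from 8640356 to 8641696, 32438 bp from Pum2 (39.2). The distal share depended on the list and the distance, at 18.8% in the replicate 2 list, 17.6% for a distance of 2000 bp, 7.48% for 10000 bp and 17.4% with the TSSs of protein-coding genes only.

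Few genes were marked in a single replicate. The replicate 1 list marked 100 genes that replicate 2 did not, and replicate 2 marked 349 that replicate 1 did not, 449 in all; this compares 2 libraries, not conditions. The strongest peaks at such genes in replicate 2 were at Sftpc (signal 49.9), Oscar (40.3), Igflr1 (35.2), Tnnc1 (34.8) and Lor (33.9). In each of these 5 cases a replicate 1 peak overlapped that peak, and the nearest replicate 1 peak lay 92, 109, 208, 21 and 13 bp outside the TSS window. In replicate 1 the strongest were B3gnt4 (18.7), Chrm1 (9.70), Nudt11 (5.88), Foxb1 (5.15) and Lgals3bp (4.85), and for B3gnt4, Chrm1 and Nudt11 a replicate 2 peak overlapped that peak and the nearest lay 77 to 156 bp outside the window.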

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

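The tests of the threshold explanation for the private peaks, of CpG-dense sequence and of peak joining as an explanation were chosen after the result was seen, although no joining was among the settings fixed beforehand. With a single group, no biological explanation was tested in this part.

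Peaks were also listed outside the sequences that were analysed. The replicated list held 9 peaks on 5 other sequences, more than the 3 that a count of 0 allows, although nothing predicts a count of 0 there; their median signal was 5.95 and the highest 33.3, and replicates 1 and 2 had 17 and 13 such peaks.

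Replicate 2 listed 11946 peaks without a counterpart in replicate 1. Of these, 99.3% had a signal below the median of their list, a share already fixed by the overlap by signal, so it does not test weak peaks near the calling threshold, which stay open. A GC content bias stays open as well. Private peaks away from coding TSSs had a median GC of 51.2% in replicate 2 and 52.5% in replicate 1. The difference was -1.36 percentage points (bootstrap 95% interval -1.63 to -0.93), within the 3 points set beforehand, although the interval held only negative values. Both sides of this comparison are private peaks, so it cannot tell whether GC content affected which weak peaks were called. For shared peaks GC was higher, at 56.8% in replicate 1 and 56.3% in replicate 2. With both lists reduced to their 20422 strongest peaks, 91.4% of replicate 1 and 90.2% of replicate 2 peaks overlapped. A difference in sequencing depth also stays open, since the read numbers are unknown.

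Of the 449 genes marked in a single replicate, 5.35% (24 genes, interval 3.62% to 7.83%) had a marking peak that both replicates held, so the edge of a shared peak is argued against as the main cause. For 92.4% (95% Wilson interval 89.6% to 94.5%) the marking peak overlapped no peak of the other list and had a signal below the median; since nearly all private peaks are weak, this share follows from the one before, and weak peaks near the calling threshold stay open. For the 27 genes whose marking peak was at or above the median signal the balance differed, with 17 of 27 overlapping the other list and a median distance of 208 bp from the window to the nearest peak of the other list.

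The limb regulators had wide domains. The log2 ratio of the limb transcription factor median to random lists was 1.66, and it was 1.15 when the random lists matched the CpG-dense sequence within 5000 bp of the 5′ end, 1.61 when they matched the peak signal and 1.39 without joining of neighbouring peaks, with adjusted permutation p of 0.0006, 0.0005 and 0.001. The values for peak signal and for joining argue against each of these as the whole cause, although a part of the ratio went with joining. The value for CpG-dense sequence argues only against such sequence near the 5′ end of the gene as the whole cause, and a part of the ratio went with it. Domains could lie at other TSSs or reach past 5000 bp, where such sequence was not counted, so CpG-dense sequence there stays open. The cellular makeup of the tissue stays open, since no values per cell type were analysed here.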

How the results depend on the processing

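Of the alternatives below, 1 gene per domain, random lists matched on CpG-dense sequence or on peak signal and CpG-poor promoters only were chosen after seeing the data. Over 63 results there were 556 values under alternatives. Of these, 463 kept their result, 31 were no longer past the threshold, 18 came to pass it, 31 turned direction and 13 without a test moved. For a test, a kept result means the same direction and side of the threshold. Without a test it means a fold range for counts and the replicate SD for the distal and Hox shares. For the rank correlation it means an interval around the main value that treats peaks as independent. No paired analysis was possible because there is a single group, and leaving out 1 replicate leaves a single library, whose list was used alone. The replicate overlap (81.9% to 97.1%), the share of peaks at promoters (56.0% to 78.5%), the number of marked genes (13425 to 14519), the CpG log2 odds ratio (6.50 to 7.21) and the number of genes marked in 1 replicate (301 to 476) kept their result. For both gene counts this means only the fold range, which holds 301 against 449 genes. The number of marked genes moved by more than the replicate SD of 176. The limb transcription factors kept their calls in marking (log2 odds ratio 3.81 to 5.70), breadth (log2 ratio 1.15 to 1.956) and broadest domains (5.22 to 6.05), as did limb signalling (2.48 to 5.45, 0.66 to 1.04 and 3.37 to 4.48) and Hox genes (2.48 to 5.37, 0.86 to 4.26 and 3.52 to 5.36). Read depth is unknown, so its part in any of these limits is open. Unless the construction shows it, the cause was not tested for any value that follows.

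The rank correlation of the replicates was 0.816 at a −log10 q of at least 2, 0.866 at 5, 0.824 with 50% overlap and 0.801 on the −log10 p values. The distal share was 17.6% at 2000 bp, 7.48% at 10000 bp and 17.4% with protein-coding genes only, and 13.9% to 18.8% leaving out 1 replicate at a time. The same ranges were 58.6% to 63.6% for HoxA, 35.2% to 40.6% for HoxC and 47.8% to 50.4% for HoxD.

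For marking, the log2 odds ratios at a −log10 q of at least 5 were -0.36 for endothelial genes and 1.08 for central nervous system regulators. With windows of 500 bp they were -0.37 and 1.47, and with the 5′ end of the gene only -0.17 and 0.62, with 1.04 for imprinted genes. The cardiac value was -1.23 with windows of 2500 bp and -1.48 to -0.97 leaving out 1 replicate. Among CpG-poor promoters only, which leaves fewer members in most lists, it was 2.29 for chondrogenic, -0.79 for blood, -0.79 for cardiac, -1.20 for liver, -0.79 for pluripotency and -1.62 for terminal epidermal genes.

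For breadth, 5 lists passed the threshold at a −log10 q of at least 5 and 5 with summed peak width within 5000 bp, against 8. The count was 6 without joining, 9 with joining across 3000 bp and 9 without replicate 1, where the pluripotency list was tested as well, and 9 with lists matched on CpG-dense sequence or on peak signal. The log2 ratios at a −log10 q of at least 5 were 0.25 for chondrogenic, -0.48 for myogenic, 0.014 for endothelial and -0.39 for central nervous system lists. With 1 gene per domain they were 0.37 for ectoderm, -0.44 for myogenic and 0.047 for endothelial genes. Joining across 3000 bp gave 0.70 for ectoderm, -0.056 for myogenic, 0.063 for endothelial, 0.12 for central nervous system, 0.36 for cardiac, 1.00 for liver and 0.59 for housekeeping lists. No joining gave -0.24 for ectoderm, -0.022 for chondrogenic, -0.43 for myogenic, -0.48 for nerve and crest and 0.29 for imprinted lists. Random lists matched on CpG ratio gave 0.46 for ectoderm, -0.37 for myogenic, 0.19 for endothelial and 0.14 for blood lists. Those matched on CpG-dense sequence gave -0.062 for ectoderm, 0.058 for blood, -0.68 for cardiac and -0.35 for liver lists. Those matched on peak signal gave 0.95 for ectoderm, 0.034 for myogenic, 0.58 for endothelial, 0.092 for blood, 0.39 for nerve and crest, 0.43 for central nervous system, 0.29 for cardiac, 0.70 for liver and -0.0078 for housekeeping lists. Summed width gave 0.24 for chondrogenic, -0.48 for myogenic, -0.32 for central nervous system and 0.041 for cardiac lists. Leaving out 1 replicate at a time gave 0.28 to 0.53 for chondrogenic, -0.096 to 0.21 for myogenic, -0.78 to -0.63 for cardiac and 0.23 to 0.53 for housekeeping lists.

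For the broadest domains, the log2 odds ratios at a −log10 q of at least 5 were 2.21 for chondrogenic and 1.05 for housekeeping genes. Joining across 3000 bp gave 2.17 for ectoderm, 1.42 for chondrogenic, -0.26 for blood, 3.09 for liver, 1.63 for housekeeping and 1.91 for cell cycle lists. No joining gave -1.49 for ectoderm, 1.77 for chondrogenic, -0.57 for housekeeping and 2.26 for cell cycle lists. The widest 10% gave -0.98 for endothelial genes, and the widest 2% gave 2.34 for chondrogenic and 0.67 for housekeeping genes. For nerve and crest genes the widest 2% gave 0.29, although 0 of 17 members were that broad, against 2.28% of the others. That value comes from the constant added for an empty cell and shows no excess. The blood values of -0.26 and -0.22 and the ectoderm value of -1.49 also rest on 0 broad members. Leaving out 1 replicate at a time gave -0.023 to 1.12 for endothelial, -0.22 to 1.07 for blood and 1.26 to 2.11 for cell cycle lists.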

Other observations

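The comparison of limb with central nervous system regulators, its correction for peak signal and the restriction of the downstream extent to genes with 1 annotated TSS were chosen after the result was seen.

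Some non-coding genes of the limb and of the Hox clusters carried the mark. Hottip, a non-coding RNA gene at the end of the HoxA cluster, lay in the 51587 bp domain, Hand2os1 shared the 12422 bp domain of Hand2, and Hotair in the HoxC cluster had a domain of 3670 bp (4865 and 1482 bp in replicates 1 and 2). The imprinted non-coding genes H19 and Meg3 had domains of 2956 and 1656 bp, and Malat1 and Neat1 of 8498 and 2182 bp. Away from the TSS windows of protein-coding genes, 388 of 5367 lincRNA genes (7.23%, 95% Wilson interval 6.57% to 7.95%), 118 of 1653 antisense genes (7.14%) and 102 of 414 processed transcripts (24.6%) were marked, against 85 of 9635 processed pseudogenes (0.882%). These counts include genes inside a domain that also marks a protein-coding gene. Gm14396, Gm47071 and Gm43120 lay in the domains of Hoxd11, Pitx1 and Tbx15.

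Both sexes were in the pools, and the mark was found at genes of both sex chromosomes. Of the 183 protein-coding genes of the Y chromosome 4 were marked, Ddx3y, Eif2s3y, Kdm5d and Uty, with domains of 937, 826, 958 and 1024 bp; that of Eif2s3y measured 384 bp in replicate 1 and 1552 bp in replicate 2. Xist, the RNA gene of X inactivation, had a domain of 2505 bp, and 479 of 948 protein-coding genes of the X chromosome were marked (50.5%, 95% Wilson interval 47.3% to 53.7%).

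Domains at the promoter of a single protein-coding gene mostly reached further into the gene than upstream of it. Among domains that hold the TSS windows of 1 protein-coding gene with 1 annotated TSS, 1029 of 1172 (87.8%, 95% Wilson interval 85.8% to 89.6%) reached further downstream than upstream of the TSS, with medians of 1066.5 and 453 bp. Over genes with any number of TSSs the share was 92.1% of 9572 domains, but there the distance runs from the outermost TSS, which favours the downstream side. Both shares cover only domains that contain the 5′ end of the gene. The 1425 of 12706 promoter domains with 2 or more genes were left out, so the direction is not known for them.

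A hypothesis is that domains may be wider at regulators of the sampled tissue than at regulators of another tissue. The mean log2 width was higher by 2.45 ± 0.26 (SE) at the 46 limb transcription factors than at the 22 marked central nervous system regulators, but this pair of lists was picked for comparison after their medians were seen, so this difference is no test of the hypothesis, which stays open. Longer CpG-dense sequence within 5000 bp of the 5′ end at the limb regulators is argued against for this pair. The median length of such sequence was 1700 bp at the limb and 2400 bp at the central nervous system list. With its trend removed the difference in width was 2.73 ± 0.26. Such sequence at other TSSs was not counted. The lists also differed in median peak signal, 34.4 against 8.92. With the mean of each signal decile removed the difference was 1.54 ± 0.22, so a part of it went with peak signal and a part remained. Since the pair was picked on width, the part that remained cannot test whether signal is the whole cause, which stays open.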
